A study of Mus musculus with 6 samples.

How the data were processed

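Pancreatic cells were compared between 2 sorted fractions of mice carrying a tamoxifen-inducible Ptf1a-CreER driver, an activated Kras allele and a tdTomato reporter. Tamoxifen was given at 6 weeks of age in 2 doses of 400 mg/kg, and cells were taken 90 days after activation, per the labels' protocols. Dissociated cells were stained with 33 µM C12FDG, a substrate that becomes fluorescent when cleaved by β-galactosidase, and CD45-negative, tdTomato-positive cells were sorted into a fraction negative for senescence-associated β-galactosidase (SA-βGal; here non-senescent) and a fraction with a high signal (here senescent). Both fractions came from 3 mice of which the sexes were mixed, per the labels' protocols, and each group holds 3 libraries. The replicate numbers come from the labels, which do not say that equal numbers mark the same mouse.

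Per the labels' protocols, RNA of more than 10000 cells per sample was made into 3′ libraries with an adapted CEL-Seq2 method, in which cDNA is barcoded and amplified by in vitro transcription. The submitters' processing notes name Cutadapt 1.12, TopHat2 2.0.14, HTSeq, DESeq2 and the mouse build GRCm38, whereas the series text names a human build. Of the 22048 gene identifiers, 21781 were in the mouse annotation GENCODE vM21, and 99.93% of these overlapped the annotated gene on the same chromosome, so coordinates are given on GRCm38. Whether molecular identifiers were collapsed is not given in the sources used here. The deposited table holds raw counts per gene as whole numbers, per the file headers. It also holds normalized counts, mean counts, log2 fold changes with standard errors, p-values and adjusted p-values that the authors computed. In the authors' deposited table the mean normalized count equalled the mean of these 6 libraries for 0 genes (relative tolerance 1e-06), so the authors' test appears to have drawn on other libraries, which are not analysed here. The authors' values are cited once, as theirs.

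The raw counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM scaling, filterByExpr, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are in CPM, the usual per-library scaling of counts, taken on the TMM-scaled library size, as mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Composition was compared as shares of all counts by an exact two-sided permutation test of the group means. With 3 libraries against 3 its smallest possible p is 0.1. The mouse of origin of each library is not named, so p-values measure the spread between these libraries. Intervals of low counts are exact binomial intervals at 95%, and intervals and floors (3 counts over the group) cover counting error only.

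Before the data were examined, 32 gene lists were fixed from general knowledge. A list of sex chromosome genes was kept out of the tests. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), which compares a list with all other genes, and adjusted over the 27 lists tested. Counts of members are given over all genes tested and adjusted over the list alone. The fixed lists hold 735 genes of the table, and 44 of these are in more than 1 list. The rule for named genes was also fixed then. It takes the 12 largest changes in each direction among changed genes with at least 10 CPM and groups that do not overlap, up to 4 changed members per list with at least 5 CPM, and 12 genes named in any case. Genes named outside this rule are Ctrb1, Y-linked genes, and members of the gene families and of the acinar shares described at the end.

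Total counts ranged from 4171837 to 9622238 per library. The test was tested on simulated data with 200 genes changed by known folds and 9199 genes tested. Means came from the senescent libraries and sizes from all libraries. Outside the 200 genes, only acinar and strongly lower genes kept their measured changes. The test recovered 29.2% of 65 genes changed 2-fold, 72.3% of 65 changed 4-fold and 92.4% of 66 changed 8-fold. It called 0.251% of 8750 unchanged genes. Genes were drawn independently, with a dispersion that followed their level, so these rates do not cover a library that deviates in many genes together. Replicate libraries differed by more than Poisson noise, with a chi-square per degree of freedom from 9.84 to 53.1, which amplification alone could also produce where reads were not collapsed. The alternatives were DESeq2 size factors, library size alone, other count filters, a replicate block, leaving out each library or number, other thresholds, a 1.5-fold test, DESeq2 1.42.0, limma-voom, and camera with an estimated correlation or fry for lists. Library size outside abundant genes, thinned counts and gene families read from symbol stems were added after seeing the data. The software ran under R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

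Reads shared between near-identical genes could have been split or lost in counting. Values of trypsin genes (Try4, Prss2), elastases, Ins1, hemoglobin genes, Hamp2 and the Reg family are uncertain for this reason.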

Results

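The data comprise 6 RNA libraries of lineage-labelled pancreatic cells from mice with premalignant pancreatic intraepithelial neoplasia (PanIN), 3 from the SA-βGal-negative (non-senescent) and 3 from the SA-βGal-high (senescent) fraction. The comparison asks how the transcriptome of cells sorted for a senescence-associated enzyme activity differs from that of labelled cells without it. The fractions also differed in cell type markers, with acinar genes at 78.9% of the non-senescent and 43.1% of the senescent counts. Of 26 ductal genes 19 were higher and 1 lower in the senescent libraries. The changes below therefore cannot be assigned to senescence apart from cell type. Total counts were 4171837, 5305579 and 9622238 in the non-senescent libraries and 5157294, 7826668 and 5465663 in the senescent libraries. The group means did not differ detectably (exact permutation p = 0.9).

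Transcripts of acinar cells, the enzyme-producing cells of the exocrine pancreas, took a smaller share of the senescent libraries. The acinar list (34 genes in the table) made up 78.9% ± 0.977 (SD, n = 3) of the non-senescent counts and 43.1% ± 7.17 of the senescent counts, with 38.2%, 51.3% and 39.7% in the 3 senescent libraries. The chymotrypsinogen gene Ctrb1 alone took 30.8% ± 1.65 and 18.4% ± 0.713. Mitochondrially encoded transcripts rose from 0.475% ± 0.063 to 4.93% ± 0.233 of all counts, and from 2.25% to 8.72% of the counts outside the acinar list. The share of cytosolic ribosomal protein transcripts was 0.929% ± 0.0043 and 3.47% ± 0.61, and outside the acinar list 4.42% and 6.07%. The number of genes with at least 1 count was 10042 ± 588 and 13576 ± 15.5. Counts outside the acinar list averaged 1332190 and 3431370, so the number of genes found cannot be told apart from the depth left for them. For each of these quantities the groups did not overlap, which gives an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow.

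**Figure D1:**
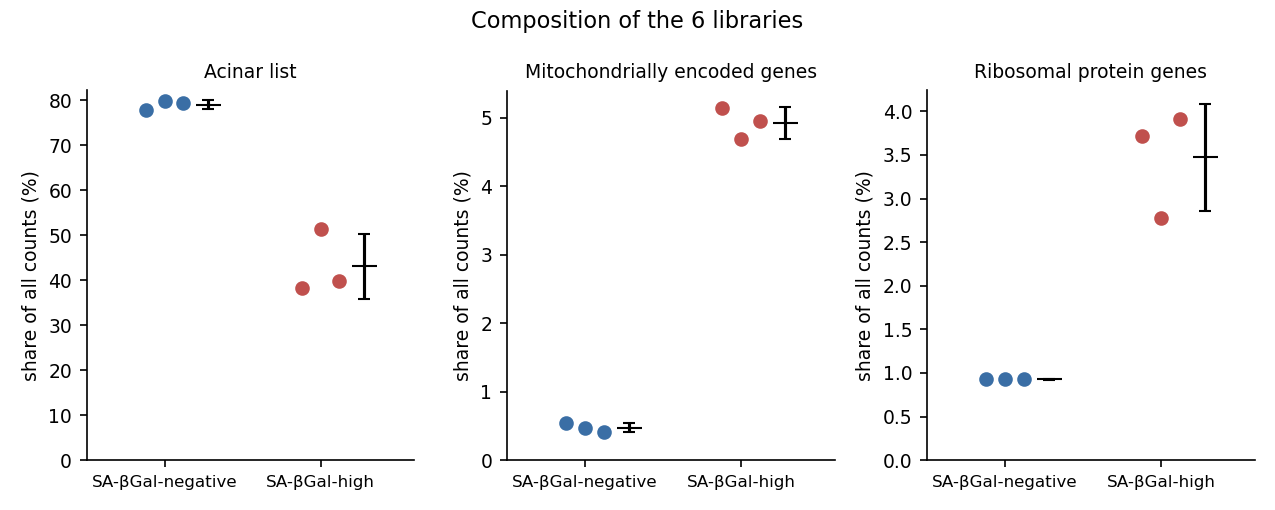
Share of all counts (%, y axis) taken by the acinar list, mitochondrially encoded genes and ribosomal protein genes in each of the 6 libraries, with the mean and SD of each group beside the points. The acinar share lay at 78.9% in the SA-βGal-negative group and 43.1% in the SA-βGal-high group, and the other shares were higher in the SA-βGal-high group.

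Of 9575 genes tested, 2602 changed between the fractions, 1380 higher and 1222 lower in the senescent libraries. Among the genes with the largest increases, Adamts1, a secreted metalloprotease, rose from 1.93 ± 1.1 to 20.6 ± 0.92 CPM (log2 fold change 3.50, SE 0.43, adjusted p = 1.0e-04). Ppy, which encodes pancreatic polypeptide, rose from 12.3 ± 4.0 to 109 ± 6.0 CPM (log2 fold change 3.19, SE 0.25, adjusted p = 4.4e-06). The others were Serpinf1 (3.76), Ptx3 (3.71), Cxcl14 (3.34), Top2a (3.24), Col1a1 (3.23), the laminin chain gene Lamc2 (3.17), Chgb (3.10), Chga (3.06), Ins1 (3.04) and Col3a1 (3.01). Of the 12 largest decreases, 7 were genes of digestive enzymes: Cela3a (-5.47), Cela1 (-4.18), Cela2a (-4.13), Pnlip (-4.12), Try4 (-4.03), Ctrl (-3.94) and Cpb1 (-3.91). Lcat (-4.24), the amino acid transporter gene Slc38a5 (-4.14), Tmed11 (-3.97), the disulfide isomerase gene Pdia2 (-3.96) and Hamp2 (-3.94) made up the rest.

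The size of several of these changes depended on single libraries. Without senescent replicate 2, Serpinf1 was at 3.16, Ptx3 at 2.58, Cxcl14 at 2.44, Col1a1 at 2.35 and Col3a1 at 1.97. Without that library Cela1 was at -4.81, Cela2a at -4.77, Pnlip at -5.03, Try4 at -4.64, Ctrl at -4.65, Tmed11 at -4.97 and Hamp2 at -5.01, all still past the threshold. Cxcl14 was at 3.97 without non-senescent replicate 1 and Lamc2 at 3.86 without non-senescent replicate 2. Cela3a, counted unevenly in the non-senescent libraries (65.1 ± 89 CPM), was at -3.19 without non-senescent replicate 3. It did not pass without senescent replicate 2 (adjusted p = 0.13) or 3 (adjusted p = 0.11), without a count filter (adjusted p = 0.09) or with the replicate block (adjusted p = 0.051). Col3a1 did not pass without a count filter (adjusted p = 0.081), nor Ptx3 (adjusted p = 0.068) and Cxcl14 (adjusted p = 0.069) with limma-voom.

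Of the 2602 changed genes, 2538 (97.5%) had groups that did not overlap, a share taken among genes that the test had selected, and 3783 genes had an unadjusted p under 0.05. The count was 1522 without senescent replicate 1, 1592 without senescent replicate 3, and between 953 and 1826 without both libraries of a number. Directions are relative to the bulk of genes, because the scaling decides them. TMM factors were 0.334 to 0.404 in the non-senescent and 2.16 to 3.07 in the senescent libraries. With library size alone the median log2 fold change was 3.06 in place of 0.17, with 9210 genes higher and 35 lower. With the library size outside 98 abundant genes, 2131 were higher and 808 lower. Of the 1222 genes lower here, 35 were also lower with library size alone, among them the 12 largest decreases, and 934 were higher.

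**Figure D2:**
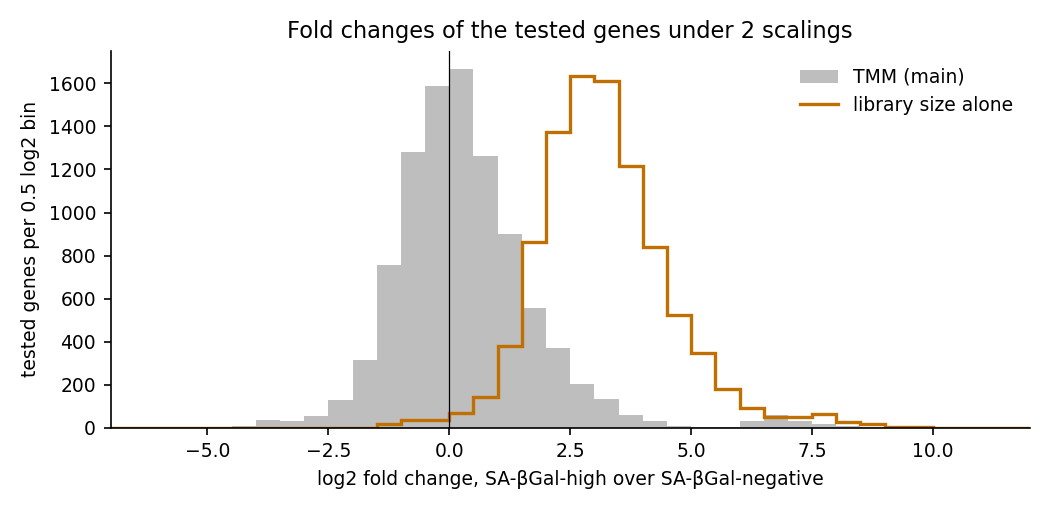
Number of tested genes (y axis, per bin of 0.5) by log2 fold change of SA-βGal-high over SA-βGal-negative libraries (x axis), with TMM scaling (filled) and with library size alone (line). The median lies at 0.17 with TMM and at 3.06 with library size alone.

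Genes of the prostaglandin pathway did not move as a set, but Ptgs2, the inducible cyclooxygenase gene (chromosome 1, 150100031 to 150108227, plus strand, ENSMUSG00000032487), was higher in the senescent libraries. It stood at 9.78 ± 6.6 against 1.1 ± 0.46 CPM (log2 fold change 3.21, SE 0.69, adjusted p = 0.0050). It had 2, 3 and 2 counts in the non-senescent libraries and 78, 291 and 117 in the senescent libraries. Without senescent replicate 2 its log2 fold change was 2.50. Pla2g4a, a phospholipase that releases arachidonic acid, was higher as well (log2 fold change 1.99, SE 0.36, adjusted p = 0.0019). The prostaglandin receptor gene Ptger3 was lower (-2.35, SE 0.26, adjusted p = 4.0e-05), but stood at 0.48 with library size alone. Of 13 tested members 3 were higher and 1 lower (5 and 2 adjusted over the list alone), with 2 to 4 and 1 to 2 when each library was left out. The list median was 0.64 (adjusted p = 0.69; adjusted p = 0.72 with an estimated correlation).

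Of 18 tested senescence genes and cell cycle inhibitors, 7 were higher and 0 lower (10 and 1 adjusted over the list alone), with 2 to 6 higher when each library was left out. Igfbp7, a secreted binding protein, rose from 27.5 ± 11 to 150 ± 53 CPM (log2 fold change 2.46, SE 0.31, adjusted p = 1.2e-04), and the inhibitor gene Cdkn1c from 2.63 ± 1.2 to 10.7 ± 2.2 CPM (1.92, SE 0.45, adjusted p = 0.0078). The gene of p21, Cdkn1a, was well counted at 308 ± 97 and 351 ± 89 CPM and was not shown to change (0.18, SE 0.24, adjusted p = 0.62; -0.0297 without non-senescent replicate 2). Cdkn2a, which encodes p16 and p19Arf, had 1, 0 and 0 counts against 10, 27 and 32, a ratio of 9.61 with a counting interval from 1.67 to 385 (adjusted p = 0.072). Without non-senescent replicate 1 no counts of Cdkn2a remain in that group, so the fitted log2 fold change of 6.93 (adjusted p = 0.054) is not a measured size. From 3.12 it went to 2.31 without non-senescent replicate 3 (adjusted p = 0.26). Cdkn2a passed with the library size outside abundant genes (adjusted p = 0.043). Cdkn2b had 3 counts against 130, a ratio of 6.03 from 2.02 to 29.6 (adjusted p = 0.034). This call was lost without any of the libraries except non-senescent replicate 1 (adjusted p 0.064 to 0.11). From 2.58 the log2 fold change went to 2.12 without non-senescent replicate 2, 3.23 without non-senescent replicate 3, and 2.51 to 2.65 without a senescent library, and the replicate block gave 2.63 (adjusted p = 0.10). Glb1, which encodes the lysosomal β-galactosidase behind the sorted activity, was at 9.08 ± 4.3 and 4.06 ± 1.0 CPM (-1.17, SE 0.45, adjusted p = 0.071). It passed without non-senescent replicate 2 (-1.48, adjusted p = 0.023) and with DESeq2 (adjusted p = 0.041), and stood at 1.75 with library size alone. The list median was 1.55, or 1.15 with the gene absent from the non-senescent libraries at its bound (adjusted p = 0.011; adjusted p = 0.15 with an estimated correlation). Of 24 p53 targets 5 were higher and 4 lower (6 and 4 adjusted over the list alone), with 3 to 5 and 2 to 3 when each library was left out. Their median was 0.49 (adjusted p = 0.31; adjusted p = 0.52 with an estimated correlation; adjusted p = 0.042 by fry). Pmaip1 (2.05, adjusted p = 3.4e-04) and Gadd45a (1.76, adjusted p = 0.0024) were higher, and Sesn1 was lower (-2.80, adjusted p = 0.0038) but at 0.17 with library size alone.

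Most tested genes of secreted signalling proteins were higher. Of 23 tested cytokines, chemokines and growth factors of the senescence secretome 18 were higher and 0 lower (20 and 0 adjusted over the list alone), with 12 to 17 higher when each library was left out. The median lay at 2.22, or 2.12 with genes at 0 in the non-senescent libraries set to their bound (adjusted p = 3.7e-09; adjusted p = 0.15 with an estimated correlation). The neutrophil-attracting chemokine gene Cxcl1 rose from 28.9 ± 4.1 to 153 ± 73 CPM (2.40, SE 0.30, adjusted p = 1.2e-04). Il6 had 2.03 ± 0.44 and 7.79 ± 7.5 CPM (1.93, SE 0.73, adjusted p = 0.067) and was at 0.77 without senescent replicate 2. It passed without senescent replicate 3 (2.30, adjusted p = 0.042), without a count filter, with thinned counts and with the library size outside abundant genes (adjusted p 0.017 to 0.041). Ccl2 passed (2.65, adjusted p = 0.016) but not without senescent replicate 2 (1.37, adjusted p = 0.089) or without any of the 3 non-senescent libraries (adjusted p 0.054 to 0.079), nor without a count filter (adjusted p = 0.12) or with limma-voom (adjusted p = 0.29). Cxcl1, Ccl2, Il6 and the senescence gene Igfbp7 were highest in senescent replicate 2, as were 11 of the 23 secretome genes and 20 of 22 fibroblast markers. Of 22 NF-kB targets 14 were higher and 0 lower (15 and 0 adjusted over the list alone), including Cxcl2 (2.22, adjusted p = 4.4e-05) and Tnfaip3 (2.19, adjusted p = 0.0024). The list had a median of 1.72, or 1.69 with such genes at their bound (adjusted p = 2.4e-07; adjusted p = 0.14 with an estimated correlation). Of 15 proteases and inhibitors 11 were higher and 1 lower (13 and 2 adjusted over the list alone), with 5 to 10 and 0 to 2 when each library was left out. The median of the list was 1.85 (adjusted p = 3.1e-04; adjusted p = 0.16 with an estimated correlation). Interferon response genes did not pass as a set, with 1 of 14 higher (1 adjusted over the list alone; 1 to 2 when each library was left out), a median of 1.2 and Cxcl10 at 1.65, or 2.24 without non-senescent replicate 1 (list adjusted p = 0.086; adjusted p = 0.25 with an estimated correlation), though they did without a count filter (adjusted p = 0.029) and by fry (adjusted p = 0.0053). Antigen presentation genes did not pass either, with 1 of 12 higher (1 adjusted over the list alone), B2m at 0.89 and a median of 0.10, or 0.017 to 0.741 when each library was left out (adjusted p = 0.65; adjusted p = 0.81 with an estimated correlation).

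Of 36 tested proliferation genes 20 were higher in the senescent libraries, 0 were lower and 16 did not pass (25 higher and 0 lower adjusted over the list alone; 14 to 20 higher when each library was left out). The median of the tested members was 1.95, or 1.76 with the 6 genes absent from the non-senescent libraries at their bound (adjusted p = 3.6e-07; adjusted p = 0.15 with an estimated correlation). The replication helicase gene Mcm6 rose from 2.51 ± 1.0 to 13 ± 2.0 CPM (2.43, SE 0.44, adjusted p = 0.0017). Top2a, a topoisomerase gene of dividing cells, stood at 2.73 ± 3.3 and 22.2 ± 10 CPM (3.24, SE 0.63, adjusted p = 0.0028), at 4.83 without non-senescent replicate 1 and at 2.64 without non-senescent replicate 3. Mki67 had 0, 7 and 0 counts against 208, 242 and 154, a ratio of 12 with a counting interval from 5.8 to 30.0 (adjusted p = 0.0064). Without non-senescent replicate 2 no counts of Mki67 remain in that group, and without non-senescent replicate 3 its log2 fold change was 2.71. The list had 349 counts in the non-senescent and 9493 in the senescent libraries, so the non-senescent levels are known only roughly.

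Output genes of the MAPK pathway downstream of Kras rose in 15 of 23 cases and fell in 0 (16 and 0 adjusted over the list alone). As a set they had a median of 1.80, or 1.66 with genes at 0 in the non-senescent libraries set to their bound (adjusted p = 4.5e-08; adjusted p = 0.14 with an estimated correlation). The receptor kinase gene Epha2 (2.45, adjusted p = 3.5e-04), the immediate early gene Fosl1 (2.43, adjusted p = 1.3e-04) and the growth factor gene Areg (2.38, adjusted p = 2.9e-04) were among them. Kras itself had 3.96 ± 2.8 and 7.44 ± 0.49 CPM (1.00, SE 0.49, adjusted p = 0.15) and passed without non-senescent replicate 1 (1.68, adjusted p = 0.019). Bcl2 family genes did not pass as a set, with 2 of 16 higher (1 adjusted over the list alone; 1 to 2 when each library was left out) and a median of 0.35 (adjusted p = 0.17; adjusted p = 0.29 with an estimated correlation; adjusted p = 0.0053 by fry). Wnt, Notch and Hedgehog targets had 2 of 11 higher (5 adjusted over the list alone; 0 to 3 when each library was left out), among them Hes1 (0.89, adjusted p = 0.013; adjusted p = 0.051 without non-senescent replicate 3 and 0.057 without senescent replicate 3), and a median of 1.03 (adjusted p = 0.11; adjusted p = 0.25 with an estimated correlation; adjusted p = 0.0042 by fry).

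**Figure D3:**
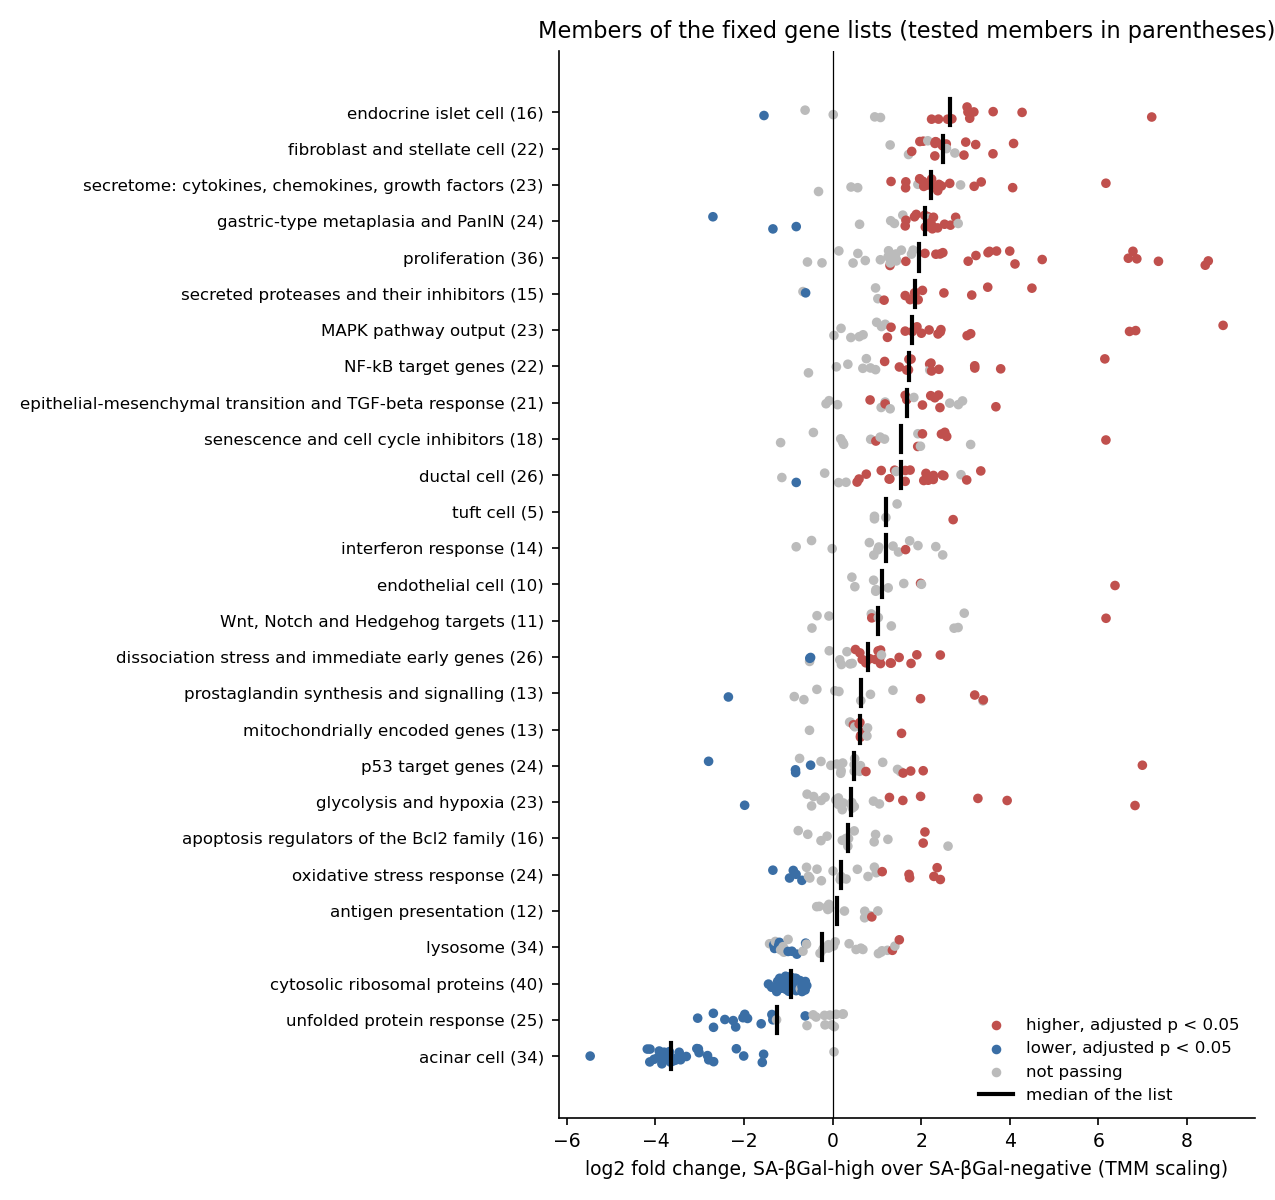
Log2 fold change of each tested member (x axis, SA-βGal-high over SA-βGal-negative, TMM scaling) by gene list (rows), with members past the threshold in color and the list median as a bar. The acinar list lies lowest with a median of -3.65 and the islet list highest with 2.65, and with library size alone the medians of the ribosomal, unfolded protein response and lysosome lists are above 0.

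Of 34 tested acinar genes 0 were higher and 33 lower (0 and 33 adjusted over the list alone). The tested members had a median of -3.65 (adjusted p = 3.5e-63; adjusted p = 0.14 with an estimated correlation). With library size alone the median was -0.81, with 21 members lower and 3 higher. The carboxypeptidase gene Cpa1 (chromosome 6, 30639218 to 30645363, plus strand, ENSMUSG00000054446) fell by a log2 fold change of -3.76 (SE 0.38, adjusted p = 1.9e-05), yet still took 7.11% ± 2.11 of the senescent counts against 13.7% ± 0.779. Of 26 ductal genes 19 were higher and 1 lower (21 and 1 adjusted over the list alone). Among the senescent libraries 20 of the 26 were highest in replicate 1 and 0 in replicate 2. The list median was 1.54 (adjusted p = 1.7e-08; adjusted p = 0.22 with an estimated correlation). The ductal keratin gene Krt19 rose from 54.6 ± 24 to 131 ± 34 CPM (1.28, SE 0.29, adjusted p = 0.0066). The transcription factor gene Onecut2 rose from 20.5 ± 3.8 to 101 ± 21 CPM, and the chloride channel gene Cftr from 5.17 ± 1.3 to 25.0 ± 9.3 CPM. Of 24 genes of gastric-type metaplasia and PanIN 15 were higher and 3 lower (18 and 3 adjusted over the list alone). In the senescent group 14 of the 24 were highest in replicate 1. The median of that list was 2.09 (adjusted p = 2.4e-07, and adjusted p = 0.15 with an estimated correlation). The trefoil factor gene Tff1 rose from 66.1 ± 18 to 452 ± 120 CPM (2.78, SE 0.24, adjusted p = 6.8e-06) and the protease gene Ctse from 35.2 ± 12 to 202 ± 53 CPM. Dmbt1 (-2.70, adjusted p = 4.4e-06; 0.18 with library size alone) was among the 3 that were lower. The mucin gene Muc5ac passed (1.89, SE 0.54, adjusted p = 0.022) but not without non-senescent replicate 1 (adjusted p = 0.066), non-senescent replicate 3 (adjusted p = 0.097) or senescent replicate 2 (1.17, adjusted p = 0.14), nor with limma-voom (adjusted p = 0.16). Of 5 tested tuft cell genes 1 was higher (1 adjusted over the list alone; 1 to 3 when each library was left out), Dclk1 at 2.72 (adjusted p = 0.0011). The median of 1.21 ranged from 0.743 to 2.98 when each library was left out, and the list passed only without non-senescent replicate 1 (adjusted p = 0.019), without a count filter (adjusted p = 0.026) or by fry (adjusted p = 0.041; adjusted p = 0.062 otherwise; adjusted p = 0.36 with an estimated correlation).

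**Figure D4:**
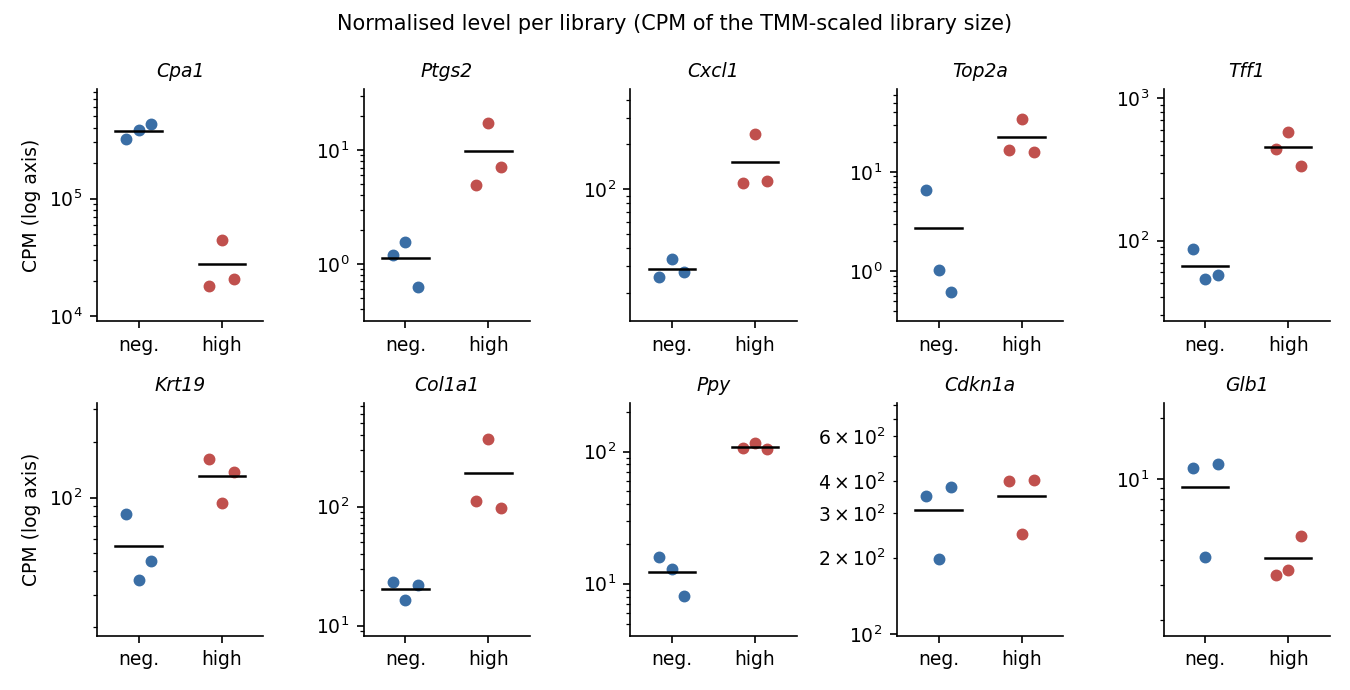
Normalised level of 10 genes in each library (CPM of the TMM-scaled library size, log axis) for the SA-βGal-negative (neg.) and SA-βGal-high (high) groups, with a line at each group mean. Cpa1 was lower and Ptgs2, Cxcl1, Top2a, Tff1, Krt19, Col1a1 and Ppy were higher in the SA-βGal-high group, while the groups overlapped for Cdkn1a and Glb1.

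Most markers of fibroblasts and islet cells were higher, although the sort had selected CD45-negative cells with the acinar lineage label. Of 22 fibroblast and stellate cell genes 17 were higher and 0 lower (22 and 0 adjusted over the list alone), but 11 were higher without senescent replicate 2. The median lay at 2.48, or 1.93 without that library (adjusted p = 4.6e-09; adjusted p = 0.25 with an estimated correlation). Bgn, a matrix proteoglycan gene, rose from 11.1 ± 2.5 to 66.4 ± 42 CPM (2.57, SE 0.41, adjusted p = 7.6e-04; 1.93 without senescent replicate 2). The fibroblast list had 20 of 22 members highest in senescent replicate 2. Of 16 islet genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone). The list had a median of 2.65, or 2.49 with genes at 0 in the non-senescent libraries set to their bound (adjusted p = 2.9e-09; adjusted p = 0.14 with an estimated correlation). Chgb, a protein of endocrine granules, rose from 7.93 ± 3.2 to 64.6 ± 13 CPM. Of 21 genes of epithelial-mesenchymal transition and the TGF-beta response 10 were higher and 0 lower (14 and 0 adjusted over the list alone), among them Ctgf (2.39, adjusted p = 0.0015) and Thbs1 (1.68, adjusted p = 4.6e-04). When each library was left out 6 to 10 were higher. The median of the list was 1.68 (adjusted p = 1.6e-04; adjusted p = 0.22 with an estimated correlation). Endothelial genes did not pass, with 2 of 10 higher (2 adjusted over the list alone; 1 to 2 when each library was left out) and a median of 1.1 (adjusted p = 0.078; adjusted p = 0.45 with an estimated correlation), but did in 4 alternatives (adjusted p 0.021 to 0.047), which left out non-senescent replicate 2, senescent replicate 1, senescent replicate 3 or the count filter.

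Blood cell markers were scarce. Macrophage genes had 3 tested members, of which 2 were higher (2 adjusted over the list alone), Apoe at 1.1 (adjusted p = 0.0049) and Cd14 at 2.05 (3.86 without non-senescent replicate 3), a call lost when any of 4 libraries was left out (adjusted p 0.057 to 0.11). The neutrophil list had 1 tested member, Ltf (1.21, adjusted p = 0.11; 1 higher adjusted over the list alone), and the lymphocyte list had 0, with 12 counts in the non-senescent and 131 in the senescent libraries. Ptprc, which encodes CD45, had 9 counts in non-senescent replicate 1 and 0 in the other libraries. Of 4 erythroid genes 0 were higher and 3 lower (0 and 4 adjusted over the list alone; 1 to 4 lower when each library was left out), Hba-a1 at -2.50 (adjusted p = 0.0032), but at 0.36 with library size alone. Of 26 dissociation stress and immediate early genes 16 were higher and 2 lower (17 and 3 adjusted over the list alone), with 11 to 16 and 0 to 2 when each library was left out. The median of its members was 0.80 (adjusted p = 1.1e-04; adjusted p = 0.32 with an estimated correlation). Ier3 (1.77, adjusted p = 2.1e-04) and Nr4a1 (1.5, adjusted p = 4.1e-04) were among those higher.

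Of 25 unfolded protein response genes 0 were higher, 13 lower and 12 did not pass (0 higher and 15 lower adjusted over the list alone). As a set they had a median of -1.26 (adjusted p = 6.7e-12, and adjusted p = 0.15 with an estimated correlation). Library size alone gave a median of 1.58, under the 3.06 of all tested genes, and the list still passed (adjusted p = 0.010). Sdf2l1, an endoplasmic reticulum chaperone component, fell from 120 ± 7.5 to 18.5 ± 4.2 CPM (-2.69, SE 0.21, adjusted p = 4.4e-06; 0.17 with library size alone). Ribosomal protein genes were lower in 39 of 40 cases (40 adjusted over the list alone). The tested members had a median of -0.93 (adjusted p = 3.9e-19; adjusted p = 0.17 with an estimated correlation). With library size alone that median was 1.96, and the list did not pass (adjusted p = 0.054). Lysosome genes were mixed, with 2 of 34 higher and 8 lower (2 and 8 adjusted over the list alone). When each library was left out 1 to 2 were higher and 6 to 9 lower. The list had a median of -0.25 (adjusted p = 0.062, and adjusted p = 0.18 with an estimated correlation). That list passed without non-senescent replicate 2 (adjusted p = 0.044) or 3 (adjusted p = 0.047), without a count filter (adjusted p = 0.026) and by fry (adjusted p = 0.0013). Its median was 2.62 with library size alone and 0.06 with the library size outside abundant genes. The cathepsin gene Ctsh was higher (1.35, adjusted p = 0.0034), and Ctsd was lower (-1.31, adjusted p = 0.0020) but at 1.65 with library size alone.

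Of 13 mitochondrially encoded genes 7 were higher and 0 lower (11 and 0 adjusted over the list alone), with 3 to 6 higher when each library was left out. The list median was 0.62 (adjusted p = 0.0093; adjusted p = 0.34 with an estimated correlation), and the list did not pass without senescent replicate 2 (0.37, adjusted p = 0.052). Glycolysis and hypoxia genes did not pass as a set, with 6 of 23 higher and 1 lower (6 and 1 adjusted over the list alone). When each library was left out 4 to 6 were higher and 1 to 2 lower. These genes had a median of 0.42 (adjusted p = 0.22, and adjusted p = 0.36 with an estimated correlation). They passed by fry (adjusted p = 0.017) and with library size alone (adjusted p = 6.8e-04). The hypoxia-induced carbonic anhydrase gene Car9 rose from 6.57 ± 3.1 to 25.2 ± 1.3 CPM. Oxidative stress genes were mixed, with 6 of 24 higher and 5 lower (6 and 5 adjusted over the list alone; 5 to 8 and 3 to 5 when each library was left out) and a median of 0.18 (adjusted p = 0.42; adjusted p = 0.45 with an estimated correlation). This list passed by fry (adjusted p = 0.0064) and with library size alone (adjusted p = 2.0e-04). The glutathione transferase gene Gsta4 (2.36, adjusted p = 6.2e-06) and the glutathione peroxidase gene Gpx2 (2.43, adjusted p = 1.0e-04) were higher.

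In the authors' deposited table, 11200 genes have an adjusted p, and 3146 of these lie under 0.05, 1939 higher and 1207 lower in the senescent fraction. Of 9546 genes in both tests, 1319 were higher and 1075 lower in both the authors' deposited table and the edgeR test, and 0 were called in opposite directions. The fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.945 and a Spearman rho of 0.998 across genes, which are not independent replicates. Both tests use these 6 libraries, and the authors' test appears to have drawn on others as well.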

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

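Library size outside abundant genes, thinned counts, gene families and library size alone for lists were chosen after seeing the data. The acinar share difference of -35.9 points ranged from -40.0 to -33.4 when each library was left out. The 2602 changed genes (1380 higher, 1222 lower) ranged from 953 to 2844 (433 to 1497 higher, 520 to 1347 lower) when a library or number was left out, and the 16 lists that passed from 15 to 18. Fewer libraries can account for lower counts. The count was 9245 (9210 higher, 35 lower) with library size alone, which does not correct for the acinar share. With library size outside abundant genes 2131 were higher and 808 lower. At an adjusted p under 0.01 the counts were 1232, 512 and 720, and with a 1.5-fold test 1529, 825 and 704, both stricter by construction. DESeq2 size factors gave 2592 genes, DESeq2 2872, limma-voom 2514, thinned counts 2002 and the other count filters 2555 and 2332. With an estimated correlation 0 of 27 lists passed, while fry, which does not compare a list with other genes, called 24. A larger correlation between members does not account for all of the lost calls. The estimates for the NF-kB (0.0081) and senescence (0.0073) lists lay under the preset 0.01. Their unadjusted camera p still went from 8.7e-08 to 0.0055 and from 0.0067 to 0.051. The other lists that had passed had estimates above the preset, and the cause was not tested further.

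With library size alone these log2 fold changes turned positive: Sesn1 0.17, Trp53inp1 2.08, Ptger3 0.48, Ctsa 1.56, Ctsd 1.65, Dmbt1 0.18, Hba-a1 0.36, Hbb-bs 0.78, Edem1 0.12, Sdf2l1 0.17, Herpud1 0.49, Bnip3 0.91, Rpl32 1.44, Rplp1 1.51, Rps8 1.66, Rpl10 1.66 and Glb1 1.75, and the medians of the lysosome (2.62), unfolded protein response (1.58) and ribosomal lists (1.96) and of the secretory pathway family (1.85). The common shift of 2.90 exceeds each decrease in size. The lysosome median was 0.0636 with library size outside abundant genes, the antigen presentation median -0.0045 with thinned counts, Cdkn1a -0.0297 without non-senescent replicate 2 (up to 0.388 without senescent replicate 2) and the oxidative stress median -0.0024 without senescent replicate 2 (up to 0.251 without senescent replicate 1). None of these last 4 had passed the threshold, and the cause was not tested.

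With the replicate number as a block 2129 genes changed (1080 higher, 1049 lower), no list changed its call, and 5 named genes lost theirs (Cela3a, Trp53, Cdkn2b, Gla and Adm). Deviations of same-numbered libraries correlated at 0.113, 0.0674 and 0.0418 across 3095 genes, and every library correlated best with its own number, a hint from the data and not from the design. The Y-linked gene Ddx3y had 1, 27 and 46 counts in non-senescent replicates 1, 2 and 3, and 1, 450 and 391 in the senescent ones. Ddx3y was thus low in both libraries numbered 1, as was Eif2s3y (0, 7 and 17 against 0, 44 and 93). Uty was low in senescent replicate 1 (1, 99 and 79 counts), but had 1, 0 and 5 in the non-senescent libraries. Kdm5d did not show this (3, 3 and 0 against 8, 19 and 11). Depth limits the genes low in the non-senescent libraries: 540 of the 1380 higher genes had fewer than 10 counts there, and 159 tested genes had 0.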

Other observations

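The gene families below and the comparison of the fibroblast and islet lists with the ductal list were chosen after the results were seen. So were the repeats of that comparison without each library, the count with Kdm5d, and the test on shares of abundant acinar transcripts. The other tests of sources below were not in the design fixed before the data were examined. They address patterns already seen, and some single out senescent replicate 1 or 2. Annexins, calcium-dependent membrane-binding proteins, and S100a proteins, their calcium-binding partners, included genes that were higher in the senescent libraries. Of 10 annexin genes 7 were higher and 1 lower, with a median log2 fold change of 1.30 (adjusted p = 1.5e-04; adjusted p = 0.070 with an estimated correlation). Anxa1 rose from 22.3 ± 5.6 to 115 ± 9.0 CPM and Anxa2 from 49.3 ± 8.1 to 220 ± 31 CPM. Of 8 S100a genes 4 were higher and 0 lower, with a median of 2.00 (adjusted p = 5.2e-04; adjusted p = 0.070 with an estimated correlation), and S100a6 rose from 94.4 ± 3.5 to 450 ± 36 CPM. Of 8 keratin genes 6 were higher and 0 lower (adjusted p = 0.0090; adjusted p = 0.32 with an estimated correlation), including Krt7 (1.64) and Krt8 (0.60), and 6 of the 8 are also in the ductal list. Of 20 collagen genes 14 were higher and 1 lower (adjusted p = 5.2e-05; adjusted p = 0.33 with an estimated correlation). As with the fibroblast list, of which 6 of them are members, most of the collagen genes (19 of 20) were highest in senescent replicate 2. Of 11 integrin genes 5 were higher and 0 lower (adjusted p = 0.0093; adjusted p = 0.25 with an estimated correlation), and of 9 laminin chain genes 3 were higher and 0 lower (adjusted p = 0.013; adjusted p = 0.23 with an estimated correlation; median 1.6, but 0.88 without senescent replicate 2).

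The 6 tested Reg genes, secreted lectin-like proteins of the exocrine pancreas, were all lower, with a median of -2.91, and -0.05 with library size alone (adjusted p = 3.4e-19; adjusted p = 0.046 with an estimated correlation). Of 35 genes of the secretory pathway (translocon, signal peptidase, signal recognition particle, cargo receptors and coat proteins) 0 were higher and 21 lower. Their median was -1.0 (adjusted p = 2.4e-12, and adjusted p = 0.091 with an estimated correlation). Library size alone gave a median of 1.85, under the 3.06 of all tested genes, and the family still passed (adjusted p = 0.023). Tmed6 fell from 326 ± 51 to 28.7 ± 12 CPM. Claudins went both ways, with 6 of 11 higher and 4 lower (adjusted p = 0.66), as did serpins, with 6 of 15 higher and 4 lower (adjusted p = 0.44; adjusted p = 0.023 with library size alone). Semaphorins and plexins had 2 of 16 higher (adjusted p = 0.089), and passed without non-senescent replicate 2 (adjusted p = 0.018) and without a count filter (adjusted p = 0.031).

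Most fibroblast and islet genes tested were higher in cells sorted for the acinar lineage label. Less dilution by acinar RNA would raise alike all genes that acinar cells do not express, a condition that was not tested for the ductal list. The fibroblast median lay 0.946 (bootstrap SE 0.285) and the islet median 1.11 (SE 0.525) above the ductal median. Without senescent replicate 2 these differences were 0.298 (SE 0.330) and 0.951 (SE 0.517), and without non-senescent replicate 3 they were 0.671 (SE 0.417) and 0.791 (SE 0.518), so dilution as the only cause stays open. Fibroblast RNA carried into the sort would keep its genes in a fixed ratio between libraries: 20 of 22 members were highest in senescent replicate 2, and the SD of their log2 excess there was 0.498 over 20 members with at least 100 senescent counts, against a bound of 0.5. With other count minimums that SD was 0.440 to 0.563, so the test does not decide, and islet genes had a smaller excess there (median 0.18 against 1.42, with 11 of 16 members highest in it). Expression by the labelled cells may also give the fibroblast median of 2.48, and these sources cannot be told apart without labels per cell.

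Of 36 proliferation genes 20 were higher in the fraction sorted as senescent (list adjusted p = 0.15 with an estimated correlation). With the senescent counts thinned to the mean TMM-scaled library size of the non-senescent libraries the list median was 2.00 (1.95 unthinned), with 18 members higher. Thinning leaves the expected fold change as it was, so this does not decide whether the 341 non-senescent counts of the tested members were too few. The excess in senescent replicate 2 was 1.18 (bootstrap SE 0.135) smaller for proliferation than for fibroblast genes, past the bound set for this test. That SE resamples genes, which are not independent, and the contrast sets a single library against senescent replicates 1 and 3. Spread between libraries is not measured by it, so fibroblasts dividing at a fixed rate stay open as the main source. Of 36 proliferation genes 21 were highest in senescent replicate 2 (median 0.24). Dividing cells among the labelled cells could give the 20 members that were higher, and bulk counts do not show which cells made these transcripts.

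Enzyme transcripts still took 43.1% of the senescent counts, which cells that retain acinar expression might contribute, a source that bulk counts cannot exclude. Free RNA with the non-senescent acinar profile as the only source would keep acinar genes in a fixed ratio. Over 34 genes their log2 fold changes had an SD of 0.981 (median SE 0.341), past the bound set for this test. Over the 23 members with at least 10000 counts that SD was 0.416 (median SE 0.330), within the same bound. The log2 ratios of the shares of these members, a measure chosen after the results, had an SD of 0.457 (median SE 0.146), past the bound. These measures disagree for the abundant transcripts. The SE of the fold changes includes differences between libraries that the members share, such as acinar shares of 38.2%, 51.3% and 39.7% in the senescent libraries. Shares of the members' sum take these out, so the result within the bound weighs less. As the share measure was chosen after the results, free RNA as their only source stays open. Shares of Reg1, Spink1, Pnliprp1, Reg2 and Prss2 were higher and that of Cpb1 lower without overlap, 6 of 23 members. Chance gives 10% for a single gene, but shares of the same sum are not independent, so that rate sets no expectation for the count. Values of Reg1, Reg2 and Prss2 are also uncertain, as their reads may be shared with near-identical genes. Barcode exchange was open to a test in senescent replicate 1 alone, which had 2 counts of Ddx3y, Eif2s3y and Uty where 16.9 would come with its acinar counts from non-senescent replicates 2 and 3 (Poisson probability 7.06e-06). That library was picked for its few Y-linked counts. With Kdm5d, which is in the fixed sex chromosome list but was left out of that test, these were 10 and 17.4 (Poisson probability 0.040). Exchange from non-senescent replicate 1, which also had few such counts, or into the other senescent libraries stays open, so this test does not cover the pattern.

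The real grouping gave 2602 changed genes and the highest of the other splits 0, but the 6 libraries have 10 splits, of which 1 reached that number, too few for a share under 0.05.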
